A study of Rattus norvegicus with 3 samples.

How the data were processed

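Total RNA from cryostat fractions of rat jejunum was extracted on silica columns and labelled by linear amplification, per the labels' protocols. The labels name both Cy3 and Cy5 for each sample. The 3 samples, 1 each of crypt, middle villus and top villus, were grouped by the tissue part in their labels. The design text names these 3 parts as what was compared, which gives 3 comparisons.

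The deposited value table holds 1 column per part and 6653 probes, on what was read from the values as a log2 scale. The highest value, 15.997, lies just under 16, the log2 of a 16-bit scanner's ceiling. How the authors normalized these deposited log2 values, and from which channel they came, is not given in the sources used here. The lower quartiles of the columns differ (6.05 in crypt, 4.15 in middle villus, 5.15 in top villus), so the columns had not been brought to a common distribution. The top villus column has 13 empty cells. The 3 scanner files, made with ScanArray Express 2.00 and LOWESS normalization per the file headers, hold 22575 spots each. None of their spots carries a name or ID and no header line names a part, so they were not used. Arrays have no read depth, and the number of arrays limits the precision.

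Of the 6653 probes, 4820 have 1 gene symbol in the platform annotation and 0 have several. The other 1833 are unnamed here, and were counted but not named. Symbols were updated through their Entrez identifiers with the RefSeq gene table of the GRCr8 assembly, which held 4806 of the 4820 and changed 0. The other 14 kept the platform symbol. These are 4379 genes, 411 of them with more than 1 probe. The genome build behind the array is not given in the sources used here, so no coordinates are stated.

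Values were compared as deposited, without further scaling. A probe counted as measured in a part when it lay at or above the lowest 25% of that column, and entered a comparison when measured in at least 1 of the 2 parts. A value below that level was set to it, so that such a difference is a bound. A gene's difference is the mean over its probes, and it is a bound if any of them is. Genes were called higher or lower at 2-fold or more. With 1 sample per part no test was possible. Probes of the same gene disagreed, in the sense that they passed 2-fold in opposite directions, in 6 of 339 genes with several probes for top villus against crypt, 11 of 326 for middle villus against crypt and 17 of 327 for top against middle villus.

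A rule on bounds was added after the first counts had been seen. The levels below which a value counted as dim differed between middle and top villus by just over the log2 difference of 1, so that a gene dim in both had passed as a 2-fold step, and a bound could take the sign opposite to the one it limits. Bounds were therefore not allowed to pass 0, and a step between parts that were both dim counted as no step. The counts under the earlier rule are given with the alternatives.

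Before the data were examined, 31 gene lists with 779 entries were fixed, of which 369 genes are on the table. For each list the median log2 difference is given with its percentile among 10000 random lists of the same size, drawn from 10 bins of mean level, where at least 5 genes were compared (26 lists for top villus against crypt). A percentile describes these 3 samples and is not a p-value. Genes named in the text are members of these lists and, for top villus against crypt, the 10 with the largest difference of each sign, and for the other comparisons the 5 of each sign. These were taken among genes measured in both parts with the same sign under median scaling and quantile normalization. Sign patterns along the column used the steps from crypt to middle villus and from middle to top villus.

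The error scale is the pooled SD of the log2 difference between probes of the same gene measured in both parts, over 206, 222 and 247 genes for the 3 comparisons in the order above. It covers differences between probes and not differences between animals or hybridisations. The steps were tested on simulated tables with this spread. Changes were placed in genes with 1 probe at or above the median level of the second-named part, 25 genes for each size and sign. The rates therefore do not cover dimmer genes. Changes of 4-fold were recovered at the 2-fold limit in 76.0% (higher) and 76.0% (lower) for top villus against crypt, in 76.0% and 80.0% for middle villus against crypt and in 80.0% and 100% for top against middle villus. Changes of 2-fold were recovered at that limit in 40% and 36%, 44% and 64%, and 28% and 68%, in the same order.

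Alternatives fixed in advance were quantile normalization, median scaling, no detection filter, probes measured in all 3 parts, a floor of 32 on the linear scale, the brightest probe of each gene, and limits of 1.5-fold and 4-fold. Scaling to a common 75th percentile, a common level of log2 6 and the earlier rule on bounds were added after the data had been seen. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.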

Results

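Gene expression was measured by microarray along the crypt-villus column of the jejunum of male Sprague-Dawley rats aged 6 weeks. The column runs from the crypt, where epithelial cells divide, to the tip of the villus, where they are shed into the lumen. Frozen tissue had been cut across the villi into sections of 10 µm, and 10 sections were joined into each fraction of 100 µm, counted from the villus top, with 7 fractions in the column. Fraction 1 (0 to 100 µm) was the top villus sample, fraction 4 (300 to 400 µm) the middle villus sample and fraction 6 (500 to 600 µm) the crypt sample. Each part had 1 sample, so none of the differences below has a replicate check and no p-value is given. The number of arrays limits the precision. The labels do not say how many animals stand behind a sample.

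The deposited table held 6653 probes with log2 values, whose medians were 7.81 in crypt, 7.83 in middle villus and 7.57 in top villus. Across probes, which are not independent replicates, Pearson's r was 0.50 between top villus and crypt, 0.68 between middle villus and crypt and 0.70 between top and middle villus. Genes were counted as higher or lower when they differed by at least 2-fold, a log2 difference of 1. A difference in which 1 part lay in the lowest 25% of its column is a bound and is written as "at least". The only error that could be estimated was the spread between probes of the same gene. The pooled SD of their log2 differences was 0.91 for top villus against crypt, 0.90 for middle villus against crypt and 1.05 for top against middle villus. A gene measured by 1 probe therefore stood outside 2 SDs at 3.55-fold, 3.49-fold and 4.27-fold in these comparisons.

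The first comparison asked how the top of the villus differed from the crypt. Most genes of fat absorption, epithelial defence and the immediate early response were higher at the top, and most genes of cell division and ribosome production were lower, as were the sugar transporters Slc2a2 and Slc2a5. Apoa1, the main protein of high-density lipoprotein, had the highest positive log2 difference among genes measured in both parts, at 9.04. Jchain, which joins the subunits of secreted immunoglobulin A and M, had the most negative, at -6.84. Of 3932 named genes compared, 939 were higher and 1554 lower at the top, against 1186 and 1349 under quantile normalization and 1082 and 1373 under median scaling. At 4-fold the counts were 477 and 866.

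Of the 19 genes compared on the list of fat absorption and chylomicron assembly, 17 were higher at the top and 1 was lower. Their median log2 difference was 2.69, at percentile 100 of random lists matched on level. After Apoa1, the apolipoproteins Apoa4, Apoc2 and Apoc3 differed by 7.40, 5.26 and 5.17. The intracellular fatty acid carriers Fabp2 and Fabp1 differed by 6.07 and 4.63, and Dgat1, which makes triglyceride, by 4.14. The exception was Lrat, which esterifies retinol, at -1.96. Rbp2, a retinol carrier, lay just inside the limit at 0.98.

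Most genes of sugar handling went the other way. Of 5 disaccharidases and hexose transporters compared, 3 were lower and 1 higher at the top, with a median of -2.996 at percentile 0.87. The fructose transporter Slc2a5 differed by -3.15 and the basolateral glucose transporter Slc2a2 by -3.78. Sucrase-isomaltase (Si) was at least 7.98-fold lower, while lactase (Lct) was at least 7.81-fold higher. Of 7 genes of fructose metabolism and gluconeogenesis, 5 were lower and 2 higher, with a median of -2.67 at percentile 0.505. Khk, which phosphorylates fructose, differed by -3.67 and Fbp1 by -2.23, whereas Pck1 was higher by 4.40. Among 13 peptidases and amino acid or peptide transporters, 7 were higher and 2 lower. The peptide transporter Slc15a1 was higher by 3.90 and Mep1a by 3.78, and Slc7a8 was lower, at -1.13.

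Genes of the dividing crypt were lower at the top. On the cell cycle and DNA replication list 26 of 27 genes were lower and none was higher, with a median of -3.64 at percentile 0. In 16 of these genes at least 1 part was dim, so that most values are bounds. Mki67, Cdk1 and Pcna were at least 38.4-fold, 40.7-fold and 43.1-fold lower. Mcm6, a subunit of the replicative helicase, was measured in both parts and differed by -4.88, and Stmn1 by -4.46. The gene inside the limit was Gmnn, at -0.48. Of 8 stem and progenitor cell markers 6 were lower and none was higher, with a median of -1.99 at percentile 4.58 (-3.95 without a detection filter). Of these 8 values 5 are bounds. Myc was at least 8.35-fold and Smoc2 at least 11.4-fold lower, and Slc12a2 differed by -2.36. Sox4 was within the limit at -0.13.

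On the list of ribosome biogenesis and translation 27 of 29 genes were lower at the top and none was higher, with a median of -2.71 at percentile 0. The ribosomal proteins Rps19 and Rpl8 differed by -5.14 and -3.51, the nucleolar protein Npm1 by -4.34 and the elongation factor Eef1a1 by -3.15. Hspe1, a mitochondrial chaperonin on the same list, differed by -5.55. Rpl10 and Eef1b2 were within the limit at -0.78 and -0.94. In cholesterol and fatty acid synthesis 9 of 15 genes were lower and 2 higher, with a median of -1.63 at percentile 3.12. Fdps differed by -4.95 and Fasn by -3.20, and Cyp51 was at least 8.59-fold lower. Me1 was higher by 2.07.

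Of 17 immediate early and stress genes 10 were higher and 2 lower, with a median of 2.96 at percentile 100. Jun, Fos and Zfp36 differed by 5.26, 3.68 and 3.38, and Egr1 and Klf6 were at least 23.3-fold and 21.7-fold higher. Ier2 was lower, at -1.57. In epithelial defence 8 of 10 genes were higher and none lower, with a median of 2.97 at percentile 99.96. The galactose-binding lectin Lgals3 differed by 7.04, B2m, the light chain of MHC class I, by 4.56, the membrane mucin Muc13 by 4.50 and Reg3b by 2.97.

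Purine and nucleoside handling split into genes far apart. Of 13 genes 7 were higher and 3 lower, with a median of 1.15 at percentile 95.21, and 3.90 without a detection filter. Adenosine deaminase (Ada), the nucleoside transporter Slc28a2 and the nucleotide phosphodiesterase Enpp3 differed by 7.14, 6.73 and 6.80. The top villus values of Ada, Epcam and Enpp3, the highest of the table at 15.997, 15.91 and 15.81, are close to the ceiling of a 16-bit scanner, so these probes may be saturated and their differences too small. Nt5e, which makes adenosine from AMP, was at least 117-fold higher, and Ampd3 at least 30.4-fold. The pyrimidine-degrading enzyme Dpyd was lower, at -2.26, and adenosine kinase (Adk) at least 11.8-fold lower. Of 19 genes of xenobiotic metabolism and efflux 9 were higher and 6 lower, with a median of 0.68 at percentile 96.355. The cytochromes Cyp3a9, Cyp3a18 and Cyp2j4 were higher by 7.83, 4.96 and 4.37. The glutathione peroxidase Gpx2 and the glutathione transferase Gstp2 were lower, at -4.26 and -4.16.

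Among ion and water transport genes 11 of 16 were higher and 3 lower (median 2.36, percentile 100). The water channel Aqp3 differed by 5.85, the carnitine transporter Slc22a5 by 4.29 and the sodium-proton exchanger Slc9a3 by 2.37, whereas the carbonic anhydrase Car4 differed by -3.66. In uptake of iron, calcium, metals and vitamins 8 of 16 genes were higher and 2 lower (median 1.42, percentile 99.55, and 2.86 without a detection filter). The zinc transporter Slc39a4 differed by 4.50, ferritin heavy chain (Fth1) by 3.65 and hephaestin (Heph) by 2.99, and the transferrin receptor Tfrc was at least 6.13-fold lower. In brush border and junction structure 8 of 15 were higher and 1 lower (median 1.53, percentile 97.005). Clca4 differed by 7.54, Epcam by 4.37, which saturation may make too small, and Krt20 by 4.07, and Krt19 was lower, at -3.12. Fatty acid oxidation had 4 of 17 genes higher and none lower, with a median of 0.14 at percentile 79.12, led by Acadl at 2.64.

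Of 13 intestinal transcription factors 4 were higher and 4 lower, with a median of -0.56 at percentile 40.025. Klf4 was higher by 3.26 and Vdr, the vitamin D receptor, at least 5.95-fold. Nr2f6 was lower, at -2.84, and Klf5 and Nr1h4 were at least 5.04-fold and 5.75-fold lower. Of 11 genes of BMP, Wnt, Hedgehog and Notch signalling 7 were higher and 3 lower, with a median of 1.55 at percentile 99.865. Smad7 differed by 3.21 and Bmp4 by 1.62, and Jag1 and Ihh were lower, at -2.80 and -1.73. Areg, counted here although it encodes a ligand of the EGF receptor, was at least 37.3-fold higher. Of 14 apoptosis genes 5 were higher and 3 lower (median 0.54, percentile 91.86). Tnfrsf1a was higher by 2.91, and Casp1 was lower, at -3.44.

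Markers of other cell types moved apart. T and NK cell markers were higher in 6 of 11 genes and lower in 1 (median 1.68, percentile 99.84, with 7 bounds). That median was 3.62 without a detection filter and 2.67 under quantile normalization. Gzma differed by 4.77 and Gzmb was at least 19.2-fold higher, against Cd3g at -3.44. Macrophage, dendritic cell and MHC class II genes were higher in 6 of 8 and lower in none (median 2.20, percentile 99.49), including RT1-Ba at 3.88 and RT1-Da at 3.47. All 3 B and plasma cell markers compared were lower (median -2.21), Derl3 and Tnfrsf17 by at least 3.60-fold and 4.63-fold. Both mast cell markers compared were lower, Mcpt1 at -2.49 and Cpa3 at least 6.44-fold.

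Of 10 smooth muscle markers 6 were measured in both parts and within the limit, 3 had bounds under it and 1 was higher (median 0.16, percentile 80.25, and 0.53 under quantile normalization), with Myh11 at 0.35 and Actg2 at 0.47. Of 10 fibroblast and extracellular matrix genes 2 were higher and 3 lower (median -0.55, percentile 40.03), and of 6 endothelial markers 2 were higher and none lower (median 0.75, percentile 88.14). Of 5 goblet cell markers 2 were lower and none higher (median 0.06, percentile 70.11, and -0.37 under quantile normalization). Tff3 and Zg16 lay at 0.06 and 0.21, and Clca1 was at least 57.4-fold lower. Of 9 enteroendocrine markers 3 were higher and none lower (median 0.99, percentile 92.37), with Tph1 at 1.87, Ghrl at 1.83 and Chga at 0.44. Among 3 Paneth cell markers Pla2g2a was at least 7.00-fold lower, and Lyz2 and Sod3 were within the limit at -0.90 and -0.16. The 1 tuft cell marker compared, Ltc4s, was at least 3.29-fold higher. No gene of the list of enteric neuron, glia and erythrocyte markers was on the table.

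**Figure D1:**
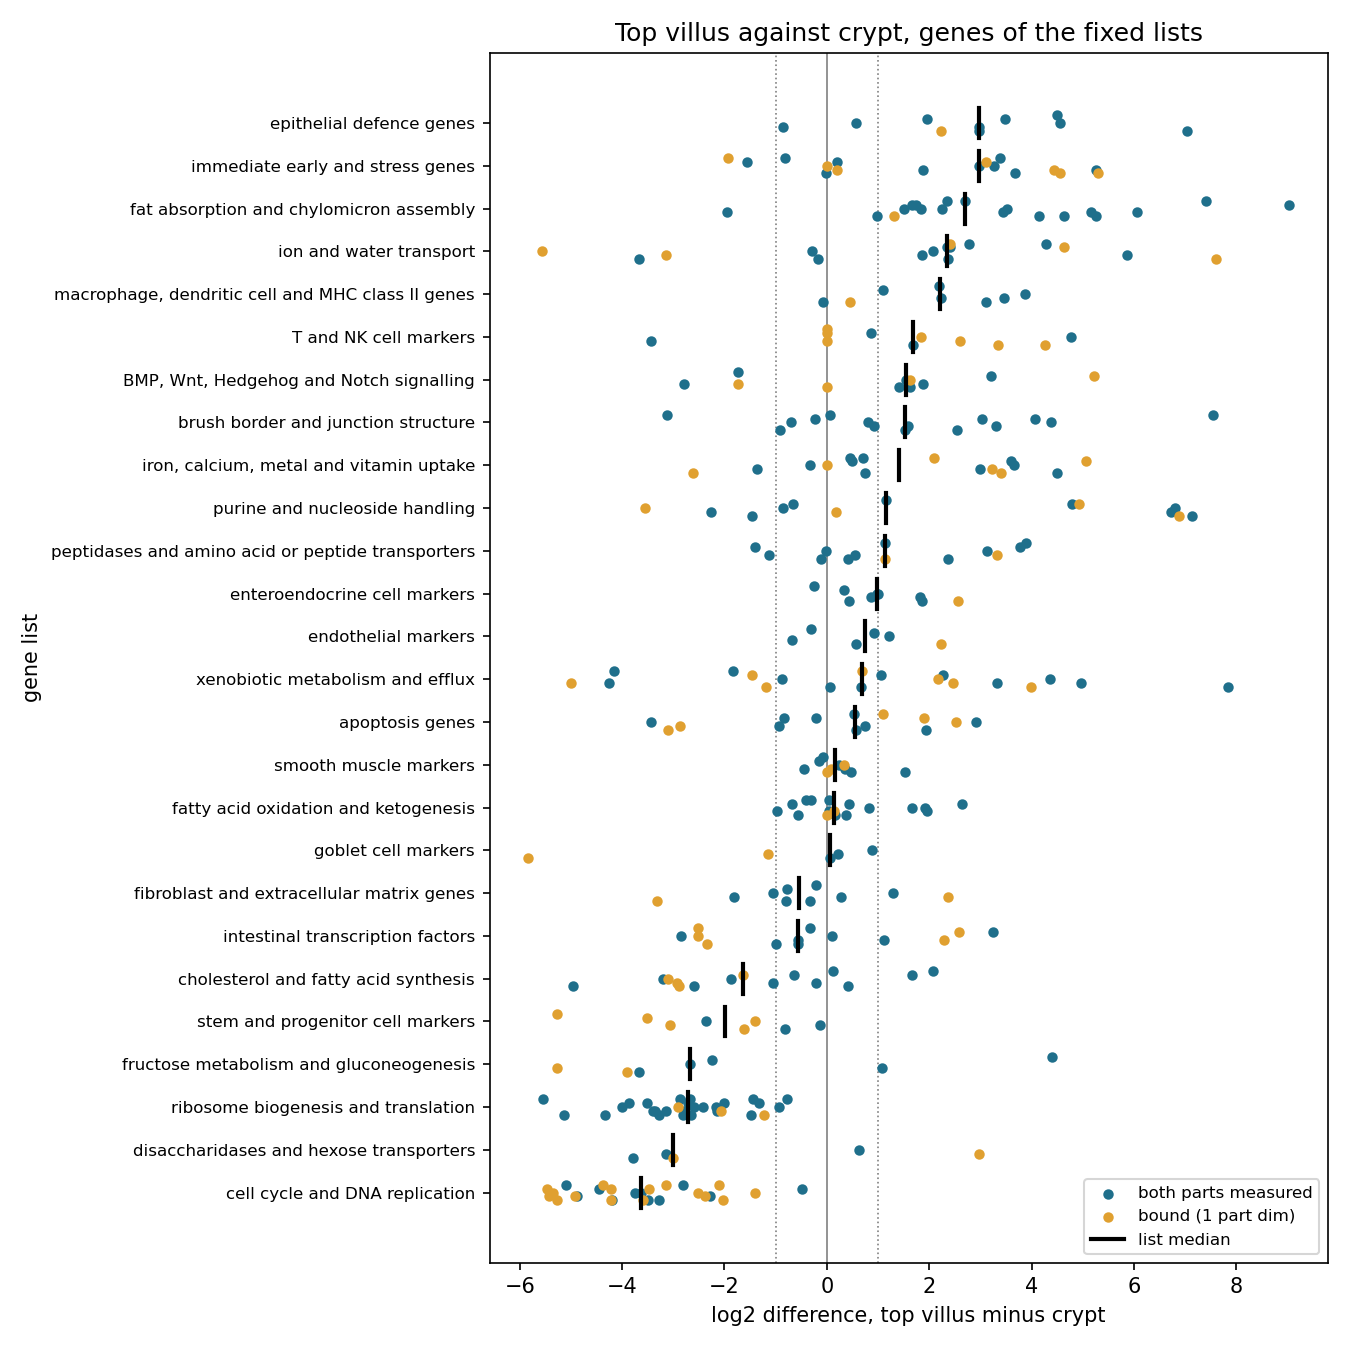
Each point is 1 gene of a fixed list, placed by its log2 difference between top villus and crypt (1 sample each), for lists with at least 5 compared genes; orange points are bounds in which 1 part was dim, black bars are list medians and dotted lines mark 2-fold. The medians run from -3.64 for cell cycle and DNA replication to 2.97 for epithelial defence.

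Outside these lists, the genes with the widest differences measured in both parts were Zfand2a (6.72) and the retinol dehydrogenase Rdh7 (6.39) on the higher side. On the lower side they were Dmbt1 (-6.72), the glutathione transferase Gsta3 (-6.52), the DNA repair enzyme Apex1 (-6.09), dopa decarboxylase Ddc (-5.59), the kinetochore protein Spc24 (-5.21) and Tmem147 (-5.16). Cdkn3, a phosphatase on the cell cycle list, differed by -5.09. The median of all genes compared was -0.39, and median scaling of the columns brought it to -0.15, so that values near 0 should be read against that shift. Among the unchanged genes of simulated tables with the measured probe spread, 23.6% passed 2-fold and 2.40% passed 4-fold. These shares follow from the spread put in. Both simulated parts came from 1 column with added noise, so the shares are no rate of false calls in these samples. Restricting the comparison to probes measured in all 3 parts left 653 genes higher and 920 lower and brought the median of cholesterol and fatty acid synthesis to -0.65, and a floor of 32 on the linear scale brought that of immediate early and stress genes to 1.69.

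The second comparison asked how the middle of the villus differed from the crypt. Most genes of peptide, fat and sugar uptake were higher in the middle villus, and most genes of the cell cycle and of ribosome production were lower. Among genes measured in both parts, Apoa1 again had the highest difference, at 9.29. It was followed by Fabp2 at 6.22, Pck1, a gluconeogenic enzyme, at 4.84, Clca4 at 4.78 and Prap1 at 4.48. The most negative genes measured in both parts were the replication licensing factor Cdt1 (-5.74), the splicing protein Snrpc (-5.53), securin (Pttg1, -5.45), Tamm41 (-5.30) and Micos10 (-5.17), the latter pair being mitochondrial. The middle villus values of Cdt1, Pttg1 and Tamm41 were 4.31, 4.62 and 4.34. These lie just above 4.15, the level below which a value there counted as dim, so their sizes and ranks depend on that level. Of 3825 named genes compared, 730 were higher and 1127 lower. At 4-fold the counts were 234 and 714.

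All 13 peptidases and amino acid or peptide transporters were higher in the middle villus than in the crypt, with a median of 2.49 at percentile 100. Dpp4 differed by 3.49, Anpep by 2.69 and Slc15a1 by 2.62. In fat absorption 16 of 19 genes were higher and 2 lower (median 2.29, percentile 100). Dgat1 differed by 4.42, and the lower pair was Lrat at -1.79 and Acsl3, an acyl-CoA synthetase, at -1.78. Of 6 disaccharidases and hexose transporters 4 were higher and 1 lower (median 2.78, percentile 100). Slc2a2 differed by 2.99 and Si and Slc2a5 by 2.80 each, Slc5a1, the sodium-glucose cotransporter, was at least 6.80-fold higher, and Slc2a1 was at least 8.58-fold lower. In fructose metabolism and gluconeogenesis 3 of 7 were higher and 1 lower (median 0.98, percentile 95.14), among them G6pc1 at 3.96.

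Ion and water transport was higher in 14 of 17 genes and lower in 1 (median 2.11, percentile 100), and uptake of iron, calcium, metals and vitamins in 13 of 16, with 2 lower (median 1.82, percentile 100). The calcium-binding protein S100g differed by 3.91 and the carotene oxygenase Bco1 by 2.97. Epithelial defence genes were higher in 8 of 11 and lower in none (median 1.87, percentile 99.95). Fatty acid oxidation genes were higher in 8 of 17 and lower in 1 (median 0.86, percentile 99.36), with Acaa2 at 2.03 and Cpt1a at least 9.58-fold lower. Xenobiotic metabolism had 8 of 19 genes higher and 4 lower (median 0.67, percentile 98.11). Brush border and junction genes were higher in 8 of 15 and lower in 1 (median 1.03, percentile 97.29).

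On the cell cycle list 26 of 27 genes were again lower and none higher (median -4.55, percentile 0), with Stmn1 at -4.55 and Fen1 at -4.07. Of these 27 values 19 are bounds, and the level for dim values was lower in middle than in top villus (4.15 against 5.15). The median is therefore no sign of a deeper fall than at the top. For probes measured in all 3 parts the medians against crypt were -3.24 in the middle and -3.22 at the top. Of 9 stem and progenitor markers 8 were lower and none higher (median -2.87, percentile 3.10, with 6 bounds), among them Hes1 at -2.33. That median was -7.50 without a detection filter and -1.85 with a common level of log2 6, chosen after seeing the data. Of the 29 genes of ribosome biogenesis and translation 24 were lower and none higher (median -2.38, percentile 0), with Nolc1 at -5.10 and Hspe1 at -3.83. Immediate early and stress genes were higher in 6 of 15 and lower in 3 (median 0.26, percentile 86.485, and 0.91 under quantile normalization or -0.0247 without a detection filter). Purine and nucleoside handling was higher in 4 of 13 and lower in 1 (median 0.04, percentile 49.41, and 1.07 under quantile normalization, 1.70 without a detection filter, 0.95 for probes measured in all 3 parts or 0.85 with a floor of 32), and of 8 smooth muscle markers none was higher and 1 lower (median 0.00464, percentile 41.9, and -0.46 without a detection filter). T and NK cell markers were higher in 7 of 10 and lower in 1 (median 1.98, percentile 100, with 6 bounds, and 3.15 without a detection filter). Macrophage and MHC class II genes were higher in 5 of 8 and lower in none (median 1.17, percentile 98.84). Of 3 B and plasma cell markers 1 was higher and 1 lower, with Jchain at 1.18, Derl3 at 0.43 and Tnfrsf17 at least 9.27-fold lower.

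Quantile normalization gave 935 genes higher and 940 lower in the middle villus, against 730 and 1127 in the values as deposited, which moved the share of higher genes among all that passed from 39.3% to 49.9%. With probes measured in all 3 parts alone, 525 genes were higher and 581 lower. Of unchanged genes in data simulated in the same way 22.0% passed 2-fold and 1.99% passed 4-fold, which again follows from the probe spread put in.

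The third comparison set the top of the villus against its middle. Most genes of sugar transport and fructose metabolism were lower at the top, most immediate early genes were higher, and 11 of 19 fat absorption genes stayed within 2-fold. Among genes measured in both parts, Slc28a2 had the highest difference, at 8.12, followed by Nt5e (6.84), Cyp4b1 (6.80), Ampd3 (6.56) and Zfand2a (6.16). The middle villus values of Cyp4b1 and Ampd3 were 4.67 and 4.41, just above 4.15, the level below which a value there counted as dim. The size and rank of both differences depend on that level. The most negative genes measured in both parts were Jchain (-8.02), Slc2a2 (-6.78), the sulfate donor synthase Papss2 (-6.77), Slc2a5 (-5.95) and Gsta3 (-5.71). Of 3768 named genes compared, 1112 were higher and 1033 lower at the top. Which side held more genes depended on the processing, with 1300 higher and 881 lower under median scaling, 953 and 1015 under quantile normalization, and 555 and 733 for probes measured in all 3 parts. At 4-fold the counts were 519 and 515.

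Of 6 disaccharidases and hexose transporters 4 were lower and 2 higher at the top (median -4.73, percentile 0). Besides Slc2a2 and Slc2a5, Si was at least 55.7-fold and Slc5a1 at least 12.7-fold lower, while Lct differed by 3.12 and Slc2a1 was at least 13.3-fold higher. In fructose metabolism and gluconeogenesis 5 of 6 genes were lower and none higher (median -3.05, percentile 0), with Khk at -3.90, Fbp1 at -3.22 and Glyctk at least 34.0-fold lower. Peptidases and amino acid or peptide transporters were lower in 7 of 13 and higher in 1 (median -1.28, percentile 0.995), with Slc7a8 at -3.17 and Dpp4 at -2.95 against Slc15a1 at 1.28. In fat absorption 7 of 19 genes were higher and 1 lower (median 0.29, percentile 83.815), and the differences of Apoa1, Fabp2 and Fabp1 were -0.26, -0.15 and 0.18. Probes of these 3 genes are among the brightest in both parts, so compression near the scanner's ceiling may hide a difference.

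Immediate early and stress genes were higher in 13 of 17 and lower in none (median 1.47, percentile 99.87). Jun differed by 3.56, Ddit3 by 3.01, Gadd45g by 2.90 and Fos by 1.47, and Hspa1a was at least 32.2-fold higher. Purine and nucleoside handling was higher in 6 of 13 and lower in 5 (median 0.47, percentile 85.955, and -0.70 for probes measured in all 3 parts), with Ada at 5.44, which saturation may make too small, and Upp1 at -2.42. Cholesterol and fatty acid synthesis was lower in 8 of 15 and higher in 1 (median -1.16, percentile 2.205), led by Fdps at -3.51. Signalling genes of the BMP, Wnt, Hedgehog and Notch list were higher in 6 of 10 and lower in 1 (median 1.36, percentile 98.08), with Bmp4 at 2.06 and Ihh at -3.66. The macrophage and MHC class II list was higher in 4 of 8 and lower in none (median 0.98, percentile 97.36), with Cd74 at 2.39, and T and NK cell markers in 5 of 12, with 2 lower (median 0.86, percentile 87.48, and 0.26 with a common level of log2 6). Of 13 cell cycle genes 6 were higher and 1 lower (median 0.46, percentile 74.46, with 7 bounds). That median was -0.0112 for probes measured in all 3 parts, -0.0318 with a common level of log2 6, 0.0263 under quantile normalization and 1.04 without a detection filter. Of 10 smooth muscle markers 3 were higher and none lower (median 0.72, percentile 85.91, and 0.19 for probes measured in all 3 parts). Of 13 transcription factors 3 were higher and 5 lower (median -0.19, percentile 39.77, and -0.80 for probes measured in all 3 parts or -1.38 without a detection filter). Of unchanged genes in data simulated in the same way 31.2% passed 2-fold and 4.96% passed 4-fold, which again follows from the probe spread put in.

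Along the whole column, 4045 genes were sorted by their steps from crypt to middle and from middle to top, each of at least 2-fold. At both steps 180 genes were higher and 164 lower. The highest value lay in the middle for 270 genes and the lowest for 343, a count that depended on how dim values were treated and ran from 147 to 900 over the alternatives at 2-fold. The first step alone passed for 280 higher and 615 lower genes, the second alone for 589 higher and 599 lower, and 1005 genes had no step of this size. A step between dim parts counts as none, which set the missing second step in 277 of the 615 genes and the missing first step in 226 of the 589. On the cell cycle list 19 of 27 genes were lower at the first step alone, 14 of them dim in both middle and top villus so that the second step could not be seen, and in fat absorption 10 of 19 were higher at the first step alone. The highest value was in the middle for 4 of 6 disaccharidases and hexose transporters (Si, Slc5a1, Slc2a2 and Slc2a5) and for 7 of 13 peptidases and amino acid or peptide transporters. Of 18 immediate early and stress genes 6 were higher at both steps.

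**Figure D2:**
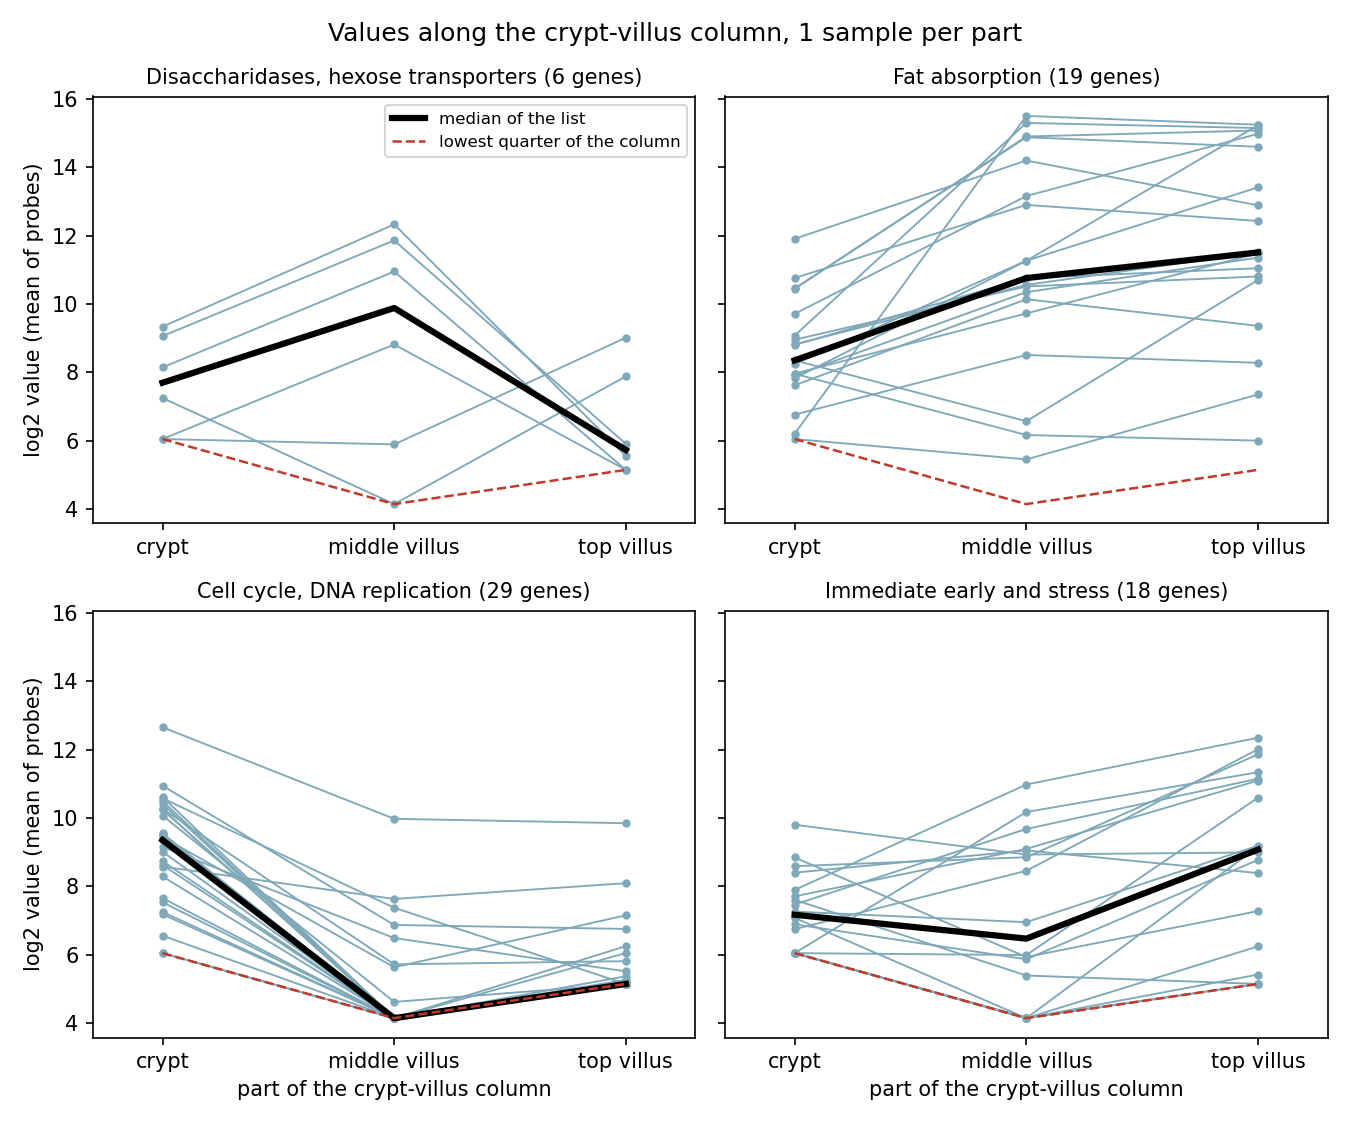
Log2 values of the genes of 4 lists in crypt, middle villus and top villus (1 sample each), with 1 thin line per gene, the list median in black and the limit of the lowest 25% of each column as a red dashed line, at which dimmer values are drawn and along which a slope has no meaning. The disaccharidase and hexose transporter lines peak in the middle for 4 of 6 genes, whereas the median difference of fat absorption genes from middle to top was 0.29.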

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

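The alternatives by 75th percentile scaling, a common level of log2 6 and bounds free to pass 0 were chosen after seeing the data. No list median of at least 1 in size and no named gene at 2-fold or more changed sign under any alternative run. List medians nearer 0 did, such as those of cell cycle and purine genes for top against middle villus, the latter going from 0.47 to -0.70 for probes measured in all 3 parts. Of 674 list medians recomputed 630 moved by less than their standard error. Of 4769 gene values 4585 moved by less than the pooled probe SD, and of 66 counts of genes 57 stayed within 1.5 times. These totals include alternatives that could hardly move a value, such as median and 75th percentile scaling, under which 0 gene values moved further. Without a detection filter 72 gene values moved further and 477 did not, and 15 list medians did and 61 did not. Quantile normalization moved 43 gene values further and a common level of log2 6 moved 41. For all values below that moved, the cause was not tested unless it follows from the alternative's construction. Signal over background limits every difference with a dim part to a bound.

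At 4-fold, which by construction admits fewer genes, 477 genes were higher and 866 lower for top villus against crypt, 234 and 714 for middle villus against crypt, and 519 and 515 for top against middle villus. The patterns then held 23 genes higher at both steps, 12 lower at both, 166 higher at the first step alone, 364 higher at the second alone, 45 highest and 132 lowest in the middle, and 2280 with no step. At 1.5-fold they held 347 higher and 380 lower at both steps, 461 highest in the middle and 443 with no step.

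Probes measured in all 3 parts, fewer by construction, gave 653 genes higher and 920 lower at the top and 525 higher and 581 lower in the middle than in the crypt, and 555 higher and 733 lower at the top than in the middle. For top against middle villus, more genes were also lower than higher under quantile normalization (953 higher, 1015 lower), with a floor of 32 (972, 1045) and with a common level of log2 6 (769, 966), whereas median scaling gave 1300 higher and 881 lower. The patterns were 229 higher at the second step alone, 262 lower at the first alone, 156 highest and 193 lowest in the middle. List medians against crypt at the top were -3.22 for cell cycle and -0.65 for cholesterol synthesis. In the middle they were -3.24 for cell cycle, 2.15 for peptidases, 2.64 for iron and vitamin uptake, 0.95 for purines (0.04 in the main analysis) and 2.70 for defence. Top against middle gave -0.0112 for cell cycle, 0.19 for smooth muscle and -0.80 for transcription factors, against 0.46, 0.72 and -0.19 in the main analysis.

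Without a detection filter, medians at the top against crypt were 3.44 for fat absorption, -4.88 for cell cycle, -3.95 for stem cells, 0.41 for smooth muscle, 3.62 for T and NK cells, 2.86 for iron and vitamin uptake and 3.90 for purines. In the middle against crypt they were -6.59 for cell cycle, -7.50 for stem cells, -0.46 for smooth muscle (0.00464 in the main analysis), 3.15 for T and NK cells, 1.70 for purines and 2.70 for defence. Top against middle gave 1.04 for cell cycle and -1.38 for transcription factors. The patterns were 300 higher and 344 lower at both steps, 356 higher at the second alone, 406 lower at the first alone and 795 lowest in the middle.

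With a common level of log2 6, cell cycle medians were -3.28 (top against crypt), -3.35 (middle against crypt) and -0.0318 (top against middle). Iron and vitamin uptake was 2.13 at the top and stem cells -1.85 in the middle against crypt, T and NK cells 0.26 at the top against the middle (0.86 in the main analysis), and 147 genes were lowest in the middle. Under quantile normalization the top against crypt gave 0.53 for smooth muscle and 2.67 for T and NK cells, and the middle against crypt -3.85 for cell cycle, 2.79 for T and NK cells, 0.91 for immediate early genes and 1.07 for purines. Cell cycle at the top against the middle was 0.0263, and 192 genes were lowest in the middle. Median scaling gave 0.37 for smooth muscle at the top against crypt. A floor of 32 gave 0.41 for smooth muscle and 1.69 for immediate early genes there, and in the middle against crypt -4.01 for cell cycle, 2.65 for T and NK cells and 0.85 for purines.

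With bounds free to pass 0, the rule used first, 900 genes were lowest in the middle, 317 higher at the second step alone and 374 lower at the first alone. Of the 557 genes lowest in the middle under that rule alone, 277 were dim in middle and top villus and 226 in crypt and middle villus, so that their step came from the limits of the columns. The other 54 had a bound that passed 0 or several probes. Not run were scanner signals in place of the table, other background corrections, and the route and dye of a ratio, because the scanner files could not be tied to parts. Leaving out a replicate was not possible with 1 sample per part. No paired analysis was possible because each part had 1 sample, and the comparisons between parts rest on no test.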

Other observations

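The gene families in this part and all tests on them were chosen after the data had been seen, and members that are no subunits, such as assembly factors and S6 kinases, were left out after first values had been seen. Genes of mitochondrial respiration were lower at the top of the villus. Of 45 genes for subunits of the respiratory complexes and ATP synthase compared, 36 were lower at the top than in the crypt and none was higher, with a median of -2.26. In the middle villus 4 of 46 were lower and 1 higher, with a median of -0.54. Mitochondrial ribosomal proteins were lower at the top than in the crypt in 33 of 36 genes (median -2.80) and protein import genes of the mitochondrial membranes in 11 of 12 (median -3.01), with none higher on either list. Cytosolic ribosomal proteins were lower in 44 of 46 (median -2.94) and in the middle villus in 37 of 46 (median -2.17). None of these medians changed sign under quantile normalization. Median and 75th percentile scaling shift all differences of a comparison by 1 constant. It was too small here to turn any of these medians, so neither scaling is a separate check.

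Proteasome subunits were lower at the top than in the crypt in 19 of 29 genes and higher in none (median -1.39), and the cytosolic chaperonin in all 3 (median -3.08). Glutathione transferases, microsomal ones included, were lower in 9 of 12 and higher in 2 (median -2.61). These directions too were kept under quantile normalization.

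Sugar genes, joining the 2 fixed lists of sugar handling, were lower at the top than in the middle villus in 9 of 12 while fat absorption genes were not, with medians of -3.44 and 0.29. This contrast and its tests were chosen after these values had been seen, so the tests say nothing on whether the contrast holds. A scaling error of the top column moves both groups alike and cannot give the gap of 3.73 (95% bootstrap interval over genes 1.77 to 6.04). Random genes of like middle villus level were not as low as the sugar genes. The central 95% of medians of random lists matched on that level ran from -1.30 to 0.82, above the observed -3.44. Because the sugar lists were picked after their low values had been seen, this does not decide on a loss that depends on signal level. Position along the villus may be the source, as a hypothesis that stays untested, since a second sample of each part, the feeding state and the animal behind each sample are not given.

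Respiration genes were lower at the top than in the middle villus in 32 of 45 and higher in 1. This fall was not particular to them. Mitochondrial ribosomal proteins were lower in 28 of 34 (median -1.67) and mitochondrial import genes in 8 of 9 (median -2.81), with none higher. Glutathione transferases were lower in 7 of 11 and higher in 2 (median -2.11), and proteasome subunits lower in 13 of 28 and higher in none (median -0.90). Scaling of the top column by 1 factor moves all genes alike and cannot give a gap between this list and all genes. Under each of the 4 scalings the interval of the list's median lay at least 1.18 below the median of all genes. Only quantile normalization is a check separate from the values as deposited, because median and percentile scaling shift all differences by 1 constant. With a family chosen after the data had been seen, the gap says nothing on whether the fall holds. The central 95% of medians of random lists matched on middle villus level ran from -0.89 to 0.21, above the observed -1.66. Because the respiration family was chosen after the data had been seen, this comparison does not decide on a loss that depends on signal level. A loss of short abundant transcripts stays open if ribosomal protein transcripts stand for these, since the respiration median minus theirs was -0.77 (interval -1.31 to -0.31), less than the SD of 1.00 among them. The RNA quality of the top fraction and a true change in the oldest cells were not tested.

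Immediate early and stress genes were higher at the top than in the middle villus in 13 of 17. The tests of this pattern were chosen after its values had been seen. Scaling by 1 factor is argued against by an interval that lay at least 0.73 above the median of all genes under each of the 4 scalings. Here too only quantile normalization is a check separate from the values as deposited. A larger share of muscle, fibroblast and endothelial cells, or of T, NK, macrophage and dendritic cells, stays open. The immediate early median was higher than that of their markers by 0.78 (interval 0.12 to 2.21) and 0.55 (0.09 to 2.56), less than the SDs of 1.57 and 1.43 among those markers. The markers were themselves higher in 10 of 27 and 9 of 20, and lower in 3 and 2. Handling of the tissue before freezing could act on the exposed tip first, and like a biological gradient along the villus it was not tested.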
